A study of Mus musculus with 39 samples.

How the data were processed

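RNA was measured by single-end sequencing of polyadenylated RNA from mouse NIH/3T3 fibroblasts in 39 libraries of 13 groups, each group described by the submitters as a biological triplicate. Per the submitters' processing notes, a fixed amount of ERCC spike-in RNA was added to RNA normalised for cell count, reads were aligned to mm9 with HISAT, and expression was summarised with Cufflinks and Cuffnorm, without versions. The deposited values are FPKM (fragments per kilobase of transcript, scaled to library size) per gene, which the authors normalised further to the spike-ins, in 1 table for the KRAS experiment (18 libraries) and 1 for the compound experiment (21 libraries). Each table held 23309 genes and 92 spike-ins, no value was 0, and in each library many genes shared 1 low value, with up to 13% of values below it (dBET6 replicate 1). The tables were normalised separately, so libraries were tested only within a table. Read counts were not used here, so the depth of each library is unknown and no interval for counting error can be given. The KRAS cells were grown with puromycin (2 µg/mL per the treatment labels).

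Genes with at least 1 FPKM in at least 3 libraries of a table were tested, 11169 in the KRAS experiment and 11055 in the compound experiment. Values were taken as log2(FPKM + 1) with the spike-in scale as deposited. Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), over all groups of an experiment and without a term for replicate number. Each of the 19 comparisons (9 in the KRAS experiment, 10 in the compound experiment) was two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are those of the fit, and FPKM are group means with the SD over 3 libraries. An exact permutation test of 3 libraries against 3 cannot give a two-sided p under 0.1, so single genes rest on the pooled spread of limma. The 19 comparisons, their tests, the gene lists and the naming of genes were chosen before the data were examined.

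The 24 gene lists were ERK pathway output, immediate early genes, Ras-associated growth factors and proteases, RAS-MAPK cascade components, G1/S and DNA replication, G2/M and mitosis, extracellular matrix, contractile and SRF/YAP targets and glycolysis. They also held cholesterol synthesis, interferon response, p53 targets, amino acid and ER stress, heat shock, BET and transcription elongation, histone genes, FKBP family and CRBN ligase, CRBN neosubstrate homologues, ribosomal proteins, NRF2 targets, and markers of macrophages, epithelium, endothelium and adipocytes. Of the RAS-MAPK list, Hras was absent from the tables. The 20 lists with at least 3 tested members were compared with all other genes by camera of limma with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Each test was repeated with a correlation estimated from the residuals, whose adjusted p is given beside the call. Counts of list members are those past the threshold over all genes tested, with the count adjusted over the list alone where it differs. In 100 simulations of unchanged groups, camera with the preset correlation called a median of 1 list, at most 8 in the KRAS experiment and 7 in the compound experiment, and with the estimated correlation 0.

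Named genes were past the threshold, had a mean of at least 5 FPKM in a compared group and had no overlap between the 3 and 3 libraries, which chance alone gives for 10% of genes. Of these, the 8 largest rises and the 8 largest falls were named (4 and 4 between treatments or times), leaving out predicted genes, clones and small RNAs. Up to 4 called members of each list that passed its test were added, and 13 genes were looked at in every comparison (Kras, Fkbp1a, Crbn, Dusp6, Spry4, Etv4, Etv5, Fosl1, Egr1, Myc, Ccnd1, Hexim1 and Brd2). Agreement between effects was taken across tested genes as Pearson's r, Spearman's rho and covariance, beside 100 simulations of unchanged groups that share the same DMSO libraries and beside the overlap of independent lists.

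The procedure was tested on simulated data with the group sizes and spread of these libraries. With 3 libraries per group, true log2 changes of 0.5, 1 and 2 were called in 26.3%, 94% and 100% of cases for dTAG-13 at 8 h in KRAS cells, with 4 of 10969 unchanged genes called. For dTAG-13 in parental cells the shares were 36.4%, 100% and 100%, with 2 of 10855 unchanged genes called. With whole-library residuals, which keep the shared scatter of a library, the shares were 24.6%, 86.6% and 100% in KRAS cells and 5.45%, 98.6% and 100% in parental cells. In 100 simulations of unchanged groups a median of 0 genes was called, 8% of the simulations in the KRAS experiment and 3% in the compound experiment called any gene. The highest count was 7756 and 48, and the median of all genes shifted by up to 0.224 and 0.232 in 95% of simulations.

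Other settings tried were a pseudocount of 0.1, no filter on low values, a stricter filter of 5 FPKM, centring of each library on its median over the tested genes, a term for the replicate number, and a fit of the compared groups alone. They also included an estimated inter-gene correlation and leaving out each library in turn, and these settings were fixed together with the comparisons. Runs without the libraries whose median stands apart, without the dBET6 libraries and with an estimated correlation on centred values were added after the data were seen. So were the comparisons of treated KRAS cells with control cells and most tests of explanations. Replicate numbers were not treated as pairs, since the labels give no pairing and the residuals of libraries with the same number correlated with a median of −0.039 and −0.028. Steps of sequencing batch or date were looked for in the labels, which give none. Positions of genes were left out because the annotation at hand is of another build than mm9. Figures were drawn with matplotlib 3.10.9 from tables written with R and with Python 3.11.15 and pandas 2.3.3.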

Results

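Polyadenylated RNA was sequenced from mouse NIH/3T3 fibroblasts in 39 libraries, with external spike-in RNA added in proportion to cell number so that the amount of mRNA per cell could be compared. The first experiment held 18 libraries in 6 groups of 3. Control cells and cells expressing a mutant KRAS fused to a degradable tag (the KRAS cells) received DMSO, and KRAS cells also received the degrader dTAG-13 (1 µM) or the MEK inhibitor trametinib (10 nM) for 4 h or 8 h. The second experiment held 21 libraries in 7 groups of 3 from parental cells treated for 4 h with DMSO, dTAG-13, dTAG-47, AP1867, ortho-AP1867 or thalidomide (each 1 µM) or with the BET protein degrader dBET6 (0.5 µM). The read depth of the libraries is unknown because the values used here are normalised. Replicates of a group correlated across genes with Pearson's r from 0.963 to 0.989 in the first experiment and from 0.979 to 0.994 in the second, and genes are not independent replicates. The number of genes tested was 11169 in the first experiment and 11055 in the second, and the median half-width of the 95% confidence interval of a log2 fold change was 0.324 and 0.313. Identities are gene symbols as deposited, and positions are not given because the reads were aligned to mm9 and the annotation at hand was of another build.

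Markers of other cell types had group means under 1 FPKM, with these exceptions. Among macrophage markers, Cd14 reached 19.8 FPKM in KRAS DMSO cells and 6.33 FPKM in parental DMSO cells, and Cd68 reached 3.81 FPKM in control cells and 3.43 FPKM in parental cells. The adipocyte marker Fabp4, a fatty acid carrier, reached 4.46 FPKM in control cells and 4.78 FPKM in parental cells. The endothelial marker Pecam1 reached 1.29 FPKM with dBET6, and every epithelial marker stayed under 1 FPKM in every group mean. These 4 lists had fewer than 3 tested members and were not tested.

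The median of a library, taken on the log2 scale over the tested genes, differed between groups as well as within them. Group means were 4.11 ± 0.058 (SD, n = 3) in control cells, 3.90 ± 0.236 in KRAS DMSO cells. With dTAG-13 at 4 h and 8 h they were 3.48 ± 0.12 and 3.90 ± 0.279, and with trametinib 3.91 ± 0.115 and 3.61 ± 0.141. In parental cells they were 4.03 ± 0.191 with DMSO, 3.78 ± 0.257 with dTAG-13, 3.86 ± 0.139 with dTAG-47, 3.85 ± 0.04 with AP1867, 4.05 ± 0.224 with ortho-AP1867, 3.79 ± 0.147 with thalidomide and 1.84 ± 0.062 with dBET6. In 6 libraries the median lay over 0.3 from the mean of the other two of the group. These were KRAS DMSO replicate 1 (3.63), KRAS dTAG-13 8 h replicates 1 and 2 (4.14 and 3.60), parental DMSO replicate 1 (4.25), parental dTAG-13 replicate 2 (3.49) and parental ortho-AP1867 replicate 1 (3.80). Each count of changed genes is therefore given with the median log2 change of all genes where that exceeded 0.1, and with the count after each library was centred on its own median.

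**Figure D1:**
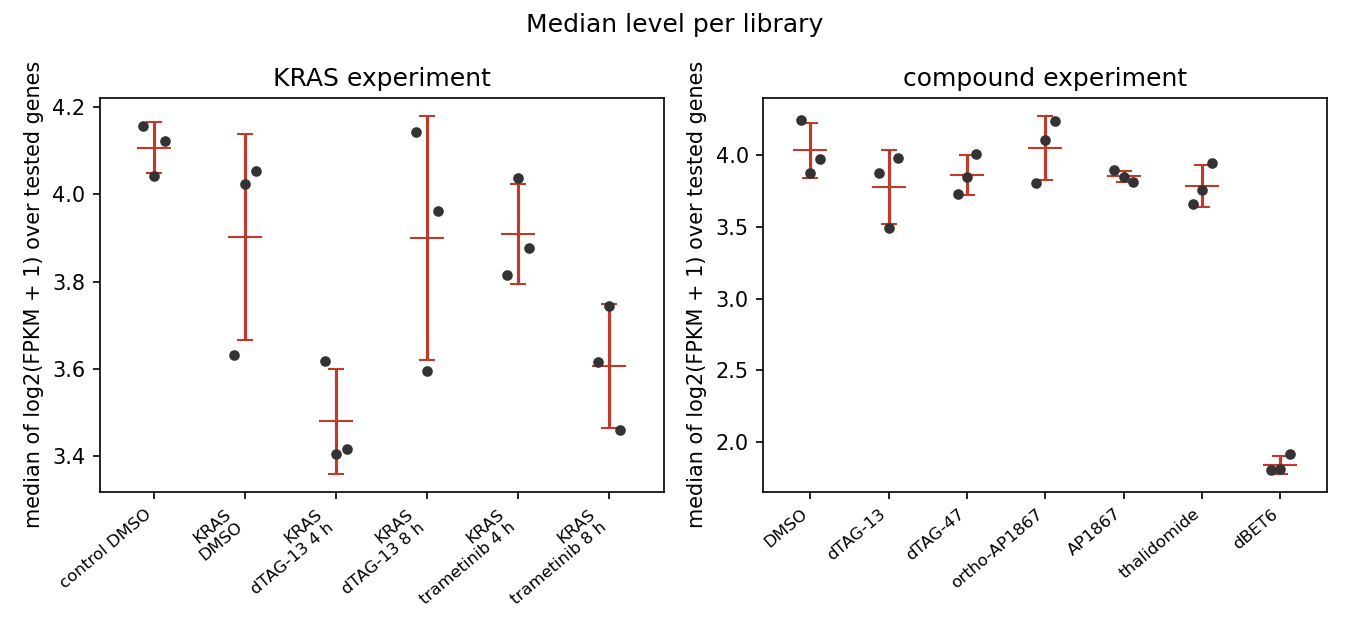
Median log2(FPKM + 1) of each library over the tested genes (vertical axis) for the 13 groups (horizontal axis), 1 point per library and the group mean ± SD in red. The dBET6 libraries stand lowest, with a mean of 1.84 against 4.03 for parental DMSO.

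The comparison of KRAS DMSO cells with control cells asks how cells with the mutant KRAS fusion differ from cells without it. The KRAS cells were grown with puromycin (2 µg/mL) and the labels of the control cells name none, so the fusion, the selection and the derivation of the line cannot be told apart in this comparison. ERK pathway output, the genes switched on by ERK together with its feedback inhibitors, was higher in KRAS cells, with 12 of 19 members risen, 3 fallen and 4 not past the threshold (adjusted over the list alone, 13 and 3). The ERK phosphatase gene Dusp6 rose from 23.1 ± 1.54 to 64.1 ± 11.7 FPKM (SD, n = 3; log2 fold change 1.42, adjusted p = 2.21e-06). Ier3 (1.38), Dusp5 (1.28) and the RAS signalling inhibitor Spry4 (1.16) rose as well, while Spry1 fell by 1.69 on the log2 scale. Ras-associated growth factors and proteases split into 10 risen, such as the EGF receptor ligands Ereg (1.94) and Hbegf (1.33), and 4 fallen, such as the chemokine genes Cxcl1 (−3.50) and Ccl2 (−2.42), or 11 and 4 adjusted over the list alone. Extracellular matrix genes fell in 16 of 19 cases and rose in 2. Col1a1 fell from 1365 ± 167 to 199 ± 63.5 FPKM and the collagen crosslinking enzyme Lox by −3.24, against rises of Lum (1.60) and Col6a3 (0.80). Of the 13 contractile and SRF/YAP targets 8 fell (9 adjusted over the list alone) and none rose, among them the smooth muscle genes Acta2 (355 ± 33.4 to 22.6 ± 4.6 FPKM) and Tagln (−3.90). Amino acid and ER stress genes fell in 10 of 14 cases, with Trib3 at −2.31, Ddit3 at −1.68 and asparagine synthetase Asns at −1.36.

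Outside the lists, the largest rises in KRAS cells were Gpr149 (70.9 ± 8.44 against 1.67 ± 0.234 FPKM, SD, n = 3), the cytokine gene Il33 (18.9 ± 1.53 against 0.160 ± 0.0463 FPKM). They were followed by Evi2a (4.05), the semaphorin Sema7a (3.80), Rgs16 (3.38), Klra18 (3.29), Ngef (3.26) and Btn1a1 (3.16). The largest falls were Tmem176b (0.187 ± 0.151 against 131 ± 10.7 FPKM), then Tmem176a (−5.53), U90926 (−4.80), the chemokine gene Cxcl5 (−4.62), Wisp2 (−4.39), the complement genes C1s (−4.20) and C1ra (−4.00), and Serpina3h (−4.18). Kras itself rose from 34.6 ± 2.3 to 84.8 ± 10.4 FPKM (adjusted p = 1.7e-06), a value that can include reads of the introduced fusion. Immediate early genes had 4 risen and 1 fallen of 16 (9 and 2 after centring), with Fosb at 1.91, Egr3 at 1.35 and Klf2 at −0.94. Egr1 did not pass (−0.16, adjusted p = 0.552). Cholesterol synthesis genes had 4 risen of 16 (12 after centring), Hmgcr (0.63) and Insig1 (0.56) among them. Ccnd1 (0.52) passed only while KRAS DMSO replicates 2 and 3 and each control replicate were kept, and Myc (−0.57) only while KRAS DMSO replicate 1 and each control replicate were kept. Fkbp1a (−0.33, a value that can likewise include reads of the fusion) and Crbn (−0.36) did not pass. Etv5 (0.16), Hexim1 (0.31) and Brd2 (−0.06) did not pass as deposited but were higher after centring, at 0.37 (adjusted p = 0.00397), 0.51 (1.03e-07) and 0.15 (0.036).

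In all 2972 genes differed between KRAS and control cells, 665 higher and 2307 lower, of which 214 and 414 by at least 2-fold. All genes had a median of −0.23 on the log2 scale, and relative to it ERK pathway output stood at 1.08. After centring 4380 genes differed, 2116 higher and 2264 lower, so the share of higher genes moved from 22.4% to 48.3%, and the count was 1819 without control replicate 1 (546 higher, 1273 lower) and 1884 without control replicate 3 (527 and 1357). Without KRAS DMSO replicate 1 813 were higher and 1175 lower, and without the libraries whose median stands apart 1030 and 1671. The set test camera placed ERK pathway output (adjusted p = 2.55e-08), growth factors and proteases (4.22e-05) and cholesterol synthesis (0.000107) above other genes. It placed extracellular matrix (2.57e-06), contractile targets (6.85e-06) and amino acid and ER stress (5.85e-05) below them, and for each of these 6 the adjusted p was 0.76 with an estimated correlation. On centred values it was 0.0409 for ERK pathway output and for contractile targets. Immediate early genes were placed above (0.00559) and ribosomal proteins below other genes (0.0324, 12 of 30 fallen, 21 adjusted over the list alone), each with adjusted p = 0.942 with an estimated correlation. The other lists were not called. They were RAS-MAPK cascade components (2 risen, 1 fallen of 15, adjusted p = 0.222), G1/S and DNA replication (0 and 1 of 20, 0.795), G2/M and mitosis (0 and 3 of 17, 0.909), and glycolysis (1 and 1 of 14, 0.0662). Nor were interferon response (0 and 4 of 9, 0 and 7 adjusted over the list alone, 0.222), p53 targets (2 and 4 of 13, 0.917), heat shock (0 and 0 of 9, 0.909) and BET and transcription elongation (1 and 1 of 14, 0.445). The remaining ones were histone genes (0 and 1 of 10, 0.909), FKBP family and CRBN ligase (0 and 3 of 12, 0.331), CRBN neosubstrate homologues (0 and 1 of 4, 0.598) and NRF2 targets (1 and 2 of 10, 0.121).

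The degrader was compared with DMSO in KRAS cells to ask what follows the loss of the fusion. At 4 h of dTAG-13, ERK pathway output fell in 18 of 19 members, with Epha4 (0.17) not past the threshold, and the same number fell when adjusted over the list alone. Dusp6 fell from 64.1 ± 11.7 to 15.1 ± 1.25 FPKM (SD, n = 3) and the cyclin gene Ccnd1 from 340 ± 74.5 to 94.1 ± 12.5 FPKM. Others fell as well, with Spry2 at −1.75, Fosl1 at −1.67, Etv5 at −1.62, Spry4 at −1.43, Etv4 at −1.13 and Myc at −1.03. Growth factors and proteases fell in 14 of 17 cases, Hbegf from 30.2 ± 5.05 to 4.63 ± 0.318 FPKM and Ereg by −2.68. G1/S and DNA replication genes fell in 17 of 20 cases (all 20 adjusted over the list alone, and 9 after centring), with the S-phase cyclin Ccne2 at −1.35 and the replication licensing factor Cdc6 at −1.13. The largest rises were Lrrc17 (16.2 ± 0.48 against 2.81 ± 0.695 FPKM), the HLH repressor Id3 (1.97), Tmem119 (1.94) and Atoh8 (1.90). Next came Rn45s (1.83), the retinoic acid hydroxylase Cyp26b1 (1.73), Fam180a (1.68) and the clock gene Dbp (1.66). The largest other falls were Sema7a (−3.58), Evi2a (−2.62), Snhg9 (−2.43, lost without dTAG-13 replicate 3 or KRAS DMSO replicate 3), Angptl4 (−2.29), Dusp5 (−2.06) and Il1rap (−2.04). Egr1 fell by 1.13, and Kras fell by 0.54 as deposited but did not pass after centring (−0.12).

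In all 5471 genes differed at 4 h, 215 higher and 5256 lower, with 30 and 459 by at least 2-fold. All genes had a median of −0.363, and after centring 4940 genes differed, 2822 higher and 2118 lower, so the share of higher genes moved from 3.93% to 57.1%. Without the libraries whose median stands apart 171 were higher and 7898 lower, and without dTAG-13 replicate 1 142 and 5411. Relative to all genes ERK pathway output stood at −0.77. Camera placed ERK pathway output (adjusted p = 4.05e-08) and growth factors and proteases (1.72e-06) below other genes (adjusted p = 0.55 with an estimated correlation for each), and G1/S genes as well (0.00443, adjusted p = 0.98 with an estimated correlation). It placed histone genes above (1.13e-07, 3 of 10 risen, 8 after centring, Hist1h2bc at 0.73, adjusted p = 0.328 with an estimated correlation). Interferon response was placed above other genes with 0 of 9 past the threshold and 6 after centring (0.000145, adjusted p = 0.458 with an estimated correlation). Extracellular matrix was placed above other genes although its median was −0.07 (0.00343, 2 risen and 6 fallen of 19, 11 and 2 after centring, adjusted p = 0.98 with an estimated correlation). So were ribosomal proteins with a median of −0.20 (0.0468, 1 fallen of 30, 0 adjusted over the list alone, 13 risen after centring, adjusted p = 0.99 with an estimated correlation). No time-matched DMSO group existed at 4 h, since the DMSO libraries carry the 8 h label.

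At 8 h of dTAG-13, ERK pathway output had 14 of 19 members fallen (15 adjusted over the list alone) and Epha4 (0.43) risen. Dusp6 stood at 20.8 ± 5.15 FPKM (SD, n = 3; −1.59), with Dusp5 at −1.40, Ccnd1 at −1.36, Fosl1 at −1.33, Etv5 at −1.17, Etv4 at −1.08 and Spry4 at −1.05. Egr1 (−0.32, adjusted p = 0.254) and Myc (−0.30, adjusted p = 0.286) did not pass as deposited and passed after centring. Growth factors and proteases fell in 12 of 17 cases and rose in 1, and G1/S genes fell in 15 of 20 (16 adjusted over the list alone), with Ccne2 at −1.33 and Ccne1 at −0.96. Matrix genes rose in 12 of 19 cases and fell in 2 (12 and 3 adjusted over the list alone), Col1a1 from 199 ± 63.5 to 617 ± 191 FPKM, Lox by 1.84 and Col3a1 by 1.64. Of the contractile targets 5 of 13 rose (9 after centring), with the YAP target Ctgf at 1.45 and the tropomyosin gene Tpm1 at 1.07. Interferon response genes rose in 5 of 9 cases (6 adjusted over the list alone), with the RNA sensor Ddx58 at 0.91 and Stat2 at 0.69, and 4 of 10 histone genes rose. The largest rises were Lrrc17 (29.7 ± 3.95 FPKM), Tmem119 (2.92), Cyp26b1 (2.73), the matrix proteoglycan gene Ogn (2.71), Atoh8 (2.42), Id3 (2.32) and Dbp (2.15), and Apoo-ps (2.36) lost its call without dTAG-13 replicate 3. The largest falls were Sema7a (−3.24), Il33 (−2.58), Evi2a (−2.49), Ereg (−2.47), the uridine phosphorylase gene Upp1 (−2.36), Ggct (−2.08), Rnf183 (−2.06) and Hbegf (−1.95).

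In all 2580 genes differed at 8 h, 1291 higher and 1289 lower, with 195 and 167 by at least 2-fold and a median of all genes of 0.01. After centring 5678 genes differed, 2907 higher and 2771 lower, and a fit of the compared groups alone called 1471 (849 and 622). The even split as deposited depended on single libraries, with 744 higher and 1610 lower without dTAG-13 replicate 1, 2244 and 834 without dTAG-13 replicate 2, and 801 and 1895 without KRAS DMSO replicate 1. It was 1213 and 812 without KRAS DMSO replicate 2, 1332 and 818 without KRAS DMSO replicate 3, and 618 and 1048 of 1666 without the libraries whose median stands apart. Camera placed ERK pathway output and G1/S genes (each adjusted p = 7.98e-09) and growth factors and proteases (5.18e-08) below other genes and interferon response above them (0.000302), each with adjusted p = 0.517 with an estimated correlation. Extracellular matrix (0.000104), contractile targets (0.00186) and histone genes (0.0119) were placed above, each with adjusted p = 0.729 with an estimated correlation. Immediate early genes were placed below (0.0393, 6 of 16 fallen, 7 adjusted over the list alone, Egr3 at −1.28 and Fosb at −1.18, adjusted p = 0.9 with an estimated correlation). Kras was at −0.22 (adjusted p = 0.316).

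Trametinib, which blocks MEK upstream of ERK, was given to the same cells as a pharmacological comparison. At 4 h ERK pathway output fell in 17 of 19 members and rose in 1, with Dusp6 at 9.46 ± 1.2 FPKM (SD, n = 3; −2.63), Etv5 at −2.96, Dusp5 at −2.33, Fosl1 at −2.22, Ccnd1 at −1.92 and Spry4 at −1.87. Immediate early genes fell in 8 of 16 cases (9 adjusted over the list alone), the transcription factor gene Egr1 from 16.8 ± 4.56 to 0.704 ± 0.143 FPKM, and Klf2 rose (1.66). Growth factors and proteases fell in 11 of 17 cases (12 adjusted over the list alone), with Ereg at −2.94 and Hbegf at −2.88, and G1/S genes in 6 of 20 (8 adjusted over the list alone, 12 after centring). Matrix genes rose in 10 of 19 cases (12 and 1 fallen adjusted over the list alone, 13 and 3 after centring), with Lox at 1.66 and Col1a1 at 1.30. Further, 4 of 13 contractile targets (5 adjusted over the list alone), 5 of 9 interferon response genes (6) and 4 of 10 histone genes rose, with Ctgf at 1.15, Isg15 at 0.81 and Hist1h1c at 0.81. The largest rises were Lrrc17 (3.12), Tmem119 (3.11), Cyp26b1 (2.95), Fam180a (2.52), the transcription factor gene Maf (2.24), Nrep (2.08), Ankrd44 (2.03) and Atoh8 (2.01). Sema7a (−4.10) and Evi2a (−2.85) were among the largest falls.

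In all 1578 genes differed with trametinib at 4 h, 764 higher and 814 lower, with 156 and 183 by at least 2-fold and a median of all genes of 0.01. After centring 4086 differed, 2062 higher and 2024 lower. Without the libraries whose median stands apart 2501 differed, 660 higher and 1841 lower, and without KRAS DMSO replicate 1 488 were higher and 1245 lower. The split was 749 and 540 without KRAS DMSO replicate 3, 640 and 538 without trametinib replicate 1, 497 and 742 without trametinib replicate 2, and 507 and 557 in a fit of the compared groups alone. Camera placed ERK pathway output (adjusted p = 1.5e-22; 0.254 with an estimated correlation), growth factors and proteases (1.04e-11; 0.343), immediate early genes (2.78e-06; 0.601) and G1/S genes (0.000108; 0.746) below other genes. It placed extracellular matrix (0.000108; adjusted p = 0.746 with an estimated correlation), interferon response (0.000307; 0.395), histone genes (0.00467; 0.601) and contractile targets (0.0338; 0.926) above. Kras was at 0.14 (adjusted p = 0.688).

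At 8 h of trametinib, ERK pathway output again had 17 of 19 members fallen and 1 risen, with Fosl1 at −2.73, Etv4 at −2.60, Dusp6 at −2.58, Etv5 at −2.32, Ccnd1 at −2.14 and Spry4 at −1.75. Immediate early genes fell in 13 of 16 cases and rose in 1 (11 and 2 after centring), with Egr1 at −3.28. All 20 G1/S genes fell, with the licensing factor Cdt1 at −1.41 and the helicase subunit Mcm3 at −1.31, as did 11 of 14 glycolysis genes, with the glucose transporter Slc2a1 at −1.56 and hexokinase Hk2 at −1.10. Ribosomal proteins fell in 26 of 30 cases (all 30 adjusted over the list alone, 21 after centring), with Rpl8 at −0.94 and Rpl18 at −0.90. Matrix genes rose in 7 of 19 cases and fell in 3 (8 and 3 adjusted over the list alone, 14 and 2 after centring), with Lox at 2.32, Col3a1 at 1.51 and Timp1 at −1.09. Interferon response genes rose in 5 of 9 cases, with Ddx58 at 1.15 (4.19 against 1.31 FPKM). The largest rises were Ogn (94.2 ± 20.3 against 8.04 ± 0.362 FPKM, SD, n = 3), Lrrc17 (3.24), Tmem119 (2.60), the proteoglycan gene Aspn (2.54), Cyp26b1 (2.36), Nrep (2.30) and Ptx3 (2.18). The largest falls were Sema7a (−4.36), Upp1 (−3.29), Ereg (−3.17), Evi2a (−3.08), the cytokine gene Clcf1 (−3.08), Hbegf (−2.99) and Rgs16 (−2.87). Kras was at −0.12 (adjusted p = 0.562), and Hexim1 did not pass as deposited and rose after centring (0.27).

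In all 4765 genes differed with trametinib at 8 h, 751 higher and 4014 lower, with 112 and 606 by at least 2-fold and a median of all genes of −0.272. Between the same groups 17 of 51 spike-ins had an unadjusted p under 0.05, against 1 with trametinib at 4 h and 1 with dTAG-13 at 8 h. None passed after adjustment, but technical differences may lie beside those of the genes. After centring 6280 differed, 3296 higher and 2984 lower, so the share of higher genes moved from 15.8% to 52.5%, and the count was 3062 without KRAS DMSO replicate 2 (645 higher, 2417 lower) and 2999 without KRAS DMSO replicate 3 (650 and 2349). The split was 837 and 2590 without trametinib replicate 3, 492 and 3944 without trametinib replicate 2, 497 and 3675 at 5 FPKM or more, and 670 and 6310 without the libraries whose median stands apart. Camera placed G1/S genes (adjusted p = 4.51e-09), ERK pathway output (6.19e-09) and growth factors and proteases (1.71e-06, 12 of 17 fallen) below other genes, each with adjusted p = 0.55 with an estimated correlation. Immediate early genes (0.000486) were placed below with adjusted p = 0.652 with an estimated correlation, and ribosomal proteins (0.00273) and glycolysis (0.0329) with 0.823. Interferon response was placed above (3.25e-06, adjusted p = 0.441 with an estimated correlation). So were extracellular matrix (2.54e-06), contractile targets (0.00116, 3 of 13 risen and 1 fallen, 9 and 0 after centring) and histone genes (0.0329, 2 risen and 1 fallen of 10, 2 and 0 adjusted over the list alone), each with adjusted p = 0.652 with an estimated correlation.

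**Figure D2:**
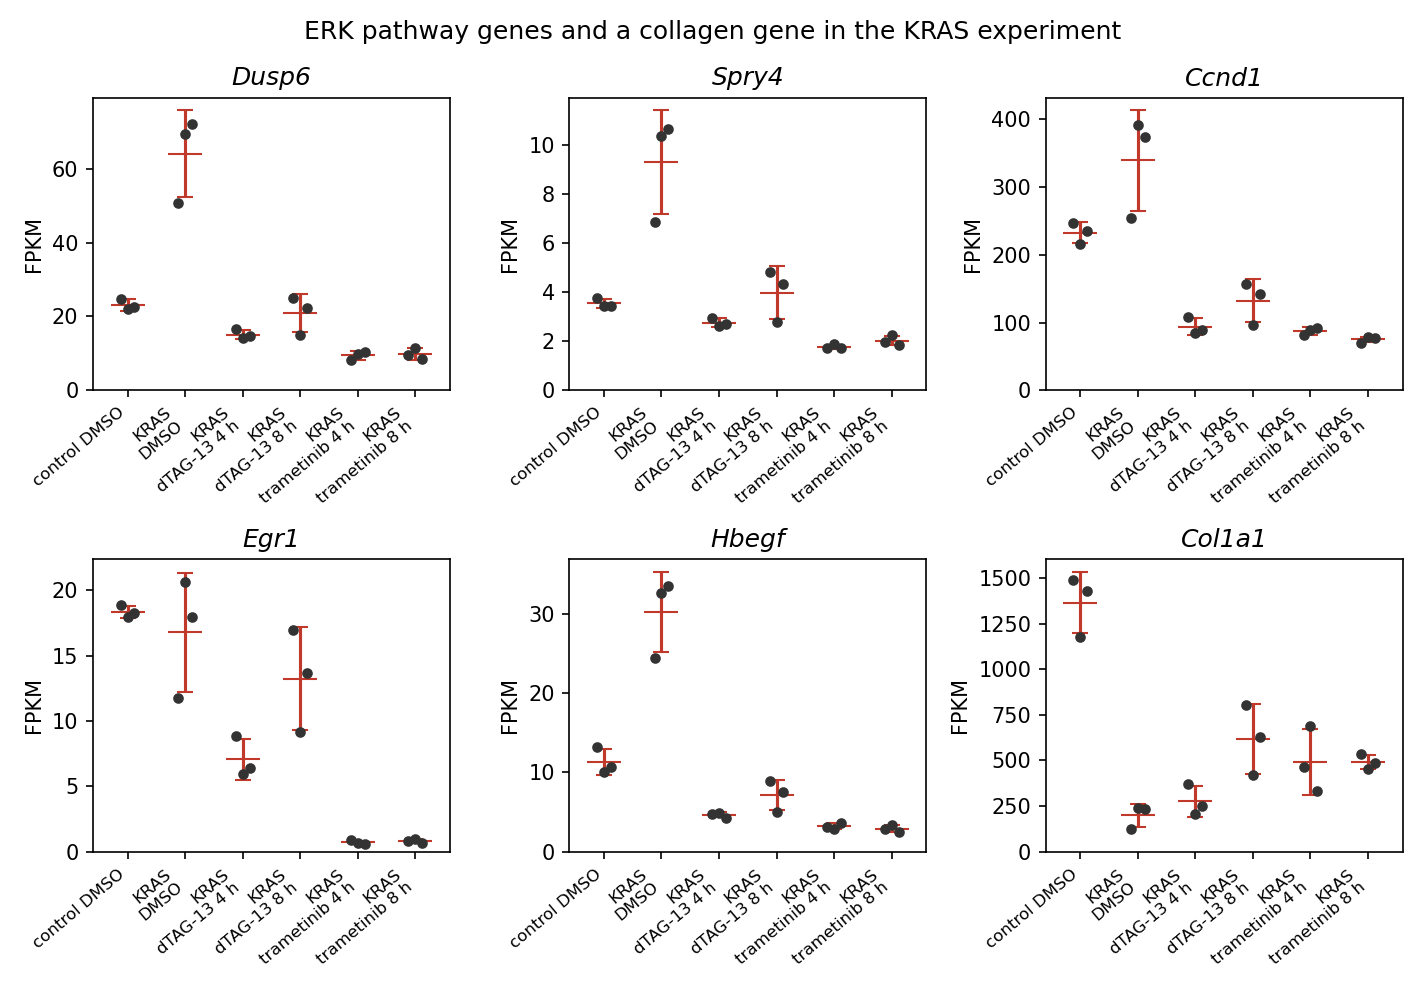
FPKM of 6 genes (vertical axes) in the 6 groups of the first experiment (horizontal axes), 1 point per library and the group mean ± SD in red. Dusp6 averaged 23.1 FPKM in control cells and 64.1 FPKM in KRAS DMSO cells, and Egr1 averaged 0.704 FPKM with trametinib at 4 h.

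The responses to dTAG-13 and trametinib share the KRAS DMSO libraries, so part of their likeness can come from those libraries. Across genes, the log2 fold changes correlated at 4 h with Pearson's r of 0.807 and Spearman's rho of 0.813 (covariance 0.14) and at 8 h with r of 0.701 and rho of 0.667 (covariance 0.163). In simulations without any treatment effect the shared DMSO libraries alone gave a mean r of 0.517 and a mean covariance of 0.0239, which leaves a covariance of 0.116 at 4 h and 0.139 at 8 h above the simulated value. At 4 h 195 genes were higher and 805 lower with both treatments, against 15 and 383 for independent lists, and at 8 h 568 and 1210, against 87 and 463. The difference between KRAS and control cells and the change with dTAG-13 at 8 h correlated with r of −0.473 and rho of −0.377, where sharing the DMSO libraries alone gave −0.517, and the covariance was −0.118 against −0.0239 simulated, a difference of −0.094. Of the genes higher in KRAS cells 367 fell with dTAG-13 at 8 h (77 for independent lists), and of those lower 674 rose (267). Another 132 went the same way in both comparisons. With trametinib at 8 h the numbers were 495 (239), 474 (155) and 421, with r −0.434 and rho −0.333. The groups of 3 left no division of the DMSO libraries with 2 in each part, so part of each excess may come from sharing them. Over both experiments 6 such correlations were computed.

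A direct comparison of dTAG-13 with trametinib asks where the degrader of the fusion and the inhibitor of MEK differed. At 4 h Egr1 was higher with dTAG-13 (7.05 ± 1.57 against 0.704 ± 0.143 FPKM, SD, n = 3; log2 2.23), as were Etv5 (1.34) and Dusp6 (0.63). As a list, 5 of 19 ERK pathway output genes were higher and 2 lower as deposited against 14 and 0 after centring. Rn45s (1.83) and the secreted BMP antagonist Grem2 (0.71) were higher, and Wnt9a (−1.62) and Bmpr2 (−1.27) were lower, while Pisd-ps1 (−2.74) and Akr1b3 (−1.59) lost their calls after centring. In all 5372 genes differed, 28 higher and 5344 lower with dTAG-13, and the median of all genes was −0.381. After centring 1226 differed, 658 higher and 568 lower. Camera placed ERK pathway output (adjusted p = 3.19e-26; 0.165 with an estimated correlation) above other genes. Immediate early genes (5.15e-09; adjusted p = 0.603 with an estimated correlation), growth factors and proteases (3.71e-06; 0.616), ribosomal proteins (2.38e-06; 0.984) and histone genes (0.000646; 0.603) were placed above other genes although their medians were −0.04, −0.17, −0.17 and −0.14. Immediate early genes went from 2 higher and 3 lower to 8 and 2 after centring, and growth factors and proteases from 2 and 4 to 7 and 1. Extracellular matrix was placed below (0.0308, 16 of 19 lower, 18 adjusted over the list alone, 3 after centring; adjusted p = 0.984 with an estimated correlation). The count fell to 2885 and 2560 without dTAG-13 replicates 2 and 3 and to 3350 and 3463 without trametinib replicates 2 and 3.

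At 8 h Egr1 was again higher with dTAG-13 (13.2 ± 3.91 against 0.790 ± 0.145 FPKM, SD, n = 3; log2 2.96, and 2.66 after centring). ERK pathway output was higher in 14 of 19 members and lower in 1 (15 and 1 adjusted over the list alone, 14 and 3 after centring), with Etv4 at 1.52, Dusp5 at 1.43, Fosl1 at 1.40 and Dusp6 at 0.99. Further, 12 of 16 immediate early genes were higher (13 adjusted over the list alone, 11 and 2 lower after centring). Ribosomal proteins were higher in 27 of 30 cases (30 adjusted over the list alone), G1/S genes in 12 of 20, growth factors and proteases in 7 of 17 (9) and NRF2 targets in 8 of 10 (10). Heme oxygenase Hmox1 stood at 0.92, and the neuropeptide gene Cck stood at 1.63. Among genes lower with dTAG-13, Atp6v0c (−1.68) kept its call under every omission of 1 library, whereas Rps27 (215 ± 301 against 3522 ± 187 FPKM) did not pass after centring. In all 3595 genes differed, 3529 higher and 66 lower, the median of all genes was 0.271, and after centring 5467 differed, 2808 higher and 2659 lower. The count was 66 without dTAG-13 replicate 1, 6340 without dTAG-13 replicate 2, 721 without dTAG-13 replicate 3, 140 without a filter on low values, 1983 without trametinib replicate 1 and 212 without trametinib replicate 3, and Egr1, Etv4, Dusp5, Fosl1, Dusp6, Cck and Hmox1 passed in each of these. Between the same groups 22 of 51 spike-ins differed, 11 higher and 11 lower, from −0.94 to 0.54, so technical differences of that size lie beside those of the genes. Camera placed ribosomal proteins (adjusted p = 2.08e-08), ERK pathway output (0.000253), immediate early genes (0.00238), G1/S genes (0.0253), NRF2 targets (0.0253) and growth factors and proteases (0.0324) above other genes, each with adjusted p = 0.971 with an estimated correlation.

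Between 4 h and 8 h of dTAG-13, the YAP targets Cyr61 (1.39) and Amotl2 (1.09), the matrix genes Ogn (1.78), Thbs1 (1.35) and Lox (1.29) and Tpm1 (1.07) rose. Matrix genes rose in 15 of 19 cases (17 adjusted over the list alone, 10 after centring with 1 fallen) and contractile targets in 7 of 13 (8 adjusted over the list alone). Col1a1 (1.15) and Egr1 (0.80) lost their calls without dTAG-13 8 h replicate 1. In all 5522 genes differed, 5513 higher and 9 lower, with a median of all genes of 0.39, and after centring 962 differed, 460 higher and 502 lower. The count was 473, 9384 and 766 without dTAG-13 8 h replicates 1, 2 and 3 and 1253 and 1298 without dTAG-13 4 h replicates 2 and 3. It was 3469 without a filter on low values and 2519 in a fit of the compared groups alone. Camera placed extracellular matrix (adjusted p = 0.000272), contractile targets (0.0169) and cholesterol synthesis (0.0457, 13 of 16 risen, 16 adjusted over the list alone, 1 after centring) above other genes. It placed glycolysis (0.00324) and heat shock genes (0.00324) below although their medians were 0.25 and 0.17 (heat shock 1 risen of 9, and 3 fallen after centring), and the adjusted p was 0.993 with an estimated correlation for each of these 5. G1/S genes (4.41e-15, median 0.05, 0 past the threshold and 12 fallen after centring; adjusted p = 0.725 with an estimated correlation) and histone genes (0.000825, median 0.29, 3 risen and 1 fallen, 0 and 3 after centring; 0.856) were placed below.

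Between 4 h and 8 h of trametinib, the proteoglycan genes Ogn (1.55), Aspn (1.47) and Omd (1.00) and the receptor gene Calcrl (0.87) rose, and Ngef (−1.62), the chromatin protein gene Hmga1 (−1.60), the chaperone gene Hspa1a (−1.36), Etv4 (−1.21), Mcm5 (−1.14) and Mcm3 (−1.08) fell. G1/S genes fell in 18 of 20 cases (19 adjusted over the list alone), ribosomal proteins in 22 of 30 (28), glycolysis genes in 10 of 14 (12), NRF2 targets in 9 of 10 and heat shock genes in 7 of 9 (8). In all 2915 genes differed, 103 higher and 2812 lower, with a median of all genes of −0.272, and after centring 4046 differed, 2074 higher and 1972 lower. Of 51 spike-ins 18 had an unadjusted p under 0.05 between these groups, and none passed after adjustment. The count was 790, 1593 and 252 without trametinib 8 h replicates 1, 2 and 3, and 1889 and 171 without trametinib 4 h replicates 1 and 2. It was 466 without a filter on low values, 5403 without the libraries whose median stands apart and 1840 with a term for the replicate number, which the labels do not give as a pairing. Camera placed G1/S genes (adjusted p = 6.32e-09), ribosomal proteins (7.35e-05), NRF2 targets (0.00276), heat shock (0.00276) and glycolysis (0.00463) below other genes, each with adjusted p = 0.949 with an estimated correlation. ERK pathway output (0.00554), extracellular matrix (0.00852), interferon response (0.00852) and contractile targets (0.0213) were placed above other genes, again with 0.949 for each, with medians of −0.02 for ERK pathway output, −0.09 for extracellular matrix and −0.13 for contractile targets. ERK pathway output had 3 risen and 3 fallen as deposited and 10 and 3 after centring, extracellular matrix 1 and 2 against 7 and 1, contractile targets 0 and 1 against 6 and 0, and interferon response 1 and 1 against 5 and 0.

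The compound experiment asks what the degraders and their parts do in cells without the fusion. With dTAG-13 none of 11055 genes passed the threshold in limma, while 2135 had an unadjusted p under 0.05 (1320 after centring) and a fit of the compared groups alone called 59, 19 higher and 40 lower. The fixed genes stood at −0.49 (Etv5), −0.47 (Etv4), −0.46 (Dusp6), −0.45 (Ccnd1), −0.43 (Fosl1), −0.38 (Spry4), −0.30 (Myc), −0.26 (Egr1), −0.25 (Fkbp1a, which encodes FKBP12), −0.20 (Kras) and −0.17 (Crbn, the ligase subunit bound by thalidomide), beside a median of all genes of −0.248. After centring 52 genes differed, 28 higher and 24 lower. The higher ones, chosen after their values were seen, included the stress response genes Chac1 (0.43), Ddit3 (0.39), Trib3 (0.36) and Herpud1 (0.25) and the cholesterol synthesis genes Idi1 (0.23) and Mvd (0.24), and the lower ones included Thbs1 (−0.32), Angptl4 (−0.31), Grem2 (−0.28) and Ccnd1 (−0.20). Camera placed ERK pathway output (adjusted p = 9.59e-09, −0.16 relative to all genes; 17 of 19 lower adjusted over the list alone) and growth factors and proteases (0.000241; 9 of 15) below other genes. Those counts include the lower median of all genes, and after centring 1 member of each list passed over all genes, Ccnd1 (adjusted p = 0.0372) and Cd44 (0.0126), while Etv5, Etv4, Dusp6, Fosl1 and Spry4 did not. It placed amino acid and ER stress (6.19e-05), histone genes (0.00025) and interferon response (0.00649) above them, and these 5 had an adjusted p of 0.8 with an estimated correlation. Cholesterol synthesis (0.00224) and p53 targets (0.0264) were placed above and contractile targets (0.00649) below, each with adjusted p = 0.973 with an estimated correlation. The count was 1 without dTAG-13 replicate 1 or 3 or without DMSO replicate 2 or 3, and FKBP family and CRBN ligase genes (0.912) and CRBN neosubstrate homologues (0.666) were not called.

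With dTAG-47 none of the genes passed in limma either, while 203 had an unadjusted p under 0.05 (1031 after centring) and a fit of the compared groups alone called 69. After centring 32 genes differed, 30 higher and 2 lower, of which 12 of the 30 were also among the 28 higher with dTAG-13. Cholesterol synthesis genes made up 11 of the 30 against 2 of the 28 with dTAG-13. They included the sterol reductase gene Dhcr7 (0.43, adjusted p = 4.7e-05), the lanosterol synthase gene Lss (0.40, adjusted p = 1.86e-05), Mvd (0.36), Idi1 (0.30) and the regulator gene Srebf2 (0.20), all chosen after their values were seen. Camera placed this list above other genes (adjusted p = 2.92e-20, 0.21 relative to all genes; 0.401 with an estimated correlation, and 3.77e-05 with that on centred values). Amino acid and ER stress (0.00335), histone genes (0.00593) and interferon response (0.00684) were placed above and ERK pathway output (0.00593), G1/S genes (0.0115) and growth factors and proteases (0.0184) below other genes, each with adjusted p = 0.868 with an estimated correlation. The median of all genes was −0.17, and the count was 1 without dTAG-47 replicate 1 or 2.

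AP1867, a synthetic ligand of FKBP12 variants, and ortho-AP1867 were compared at the same dose and time. With ortho-AP1867 1 gene passed, Rsc1a1 (5.15 ± 1.51 against 0.633 ± 0.861 FPKM, SD, n = 3; log2 2.01, adjusted p = 0.00351), which did not pass after centring or without DMSO replicate 1. Its count was 19 without ortho-AP1867 replicate 1, 2 without ortho-AP1867 replicate 3 or without DMSO replicate 3, and 4 after centring, where 1 was higher and 3 lower. It was 76 in a fit of the compared groups alone and 976 without the libraries whose median stands apart. With AP1867 none passed in limma as deposited or after centring, while 321 and 780 had an unadjusted p under 0.05, 1 passed without AP1867 replicate 2, and a fit of the compared groups alone called 84. The median of all genes was 0.02 with ortho-AP1867 and −0.174 with AP1867. Camera placed ERK pathway output (adjusted p = 0.0114), contractile targets (0.0128), extracellular matrix (0.0144), FKBP family and CRBN ligase (0.0396) and ribosomal proteins (0.044) below other genes with ortho-AP1867, each with adjusted p = 0.886 with an estimated correlation. With AP1867 it placed ERK pathway output and contractile targets (each 0.0413) below and interferon response (0.0207) and histone genes (0.0312) above, each with adjusted p = 0.963 with an estimated correlation. With thalidomide none passed in limma while 1889 had an unadjusted p under 0.05 and a fit of the compared groups alone called 63. After centring Grem2 (−0.27) and Phldb2 (−0.26) were lower, both chosen after their values were seen. The median of all genes was −0.247 with thalidomide, growth factors and proteases and G2/M genes were placed below other genes (each adjusted p = 0.00247; 0.968 with an estimated correlation), and 2 genes passed without thalidomide replicate 2.

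Compounds were also compared with each other at 1 µM and 4 h. Between dTAG-13 and ortho-AP1867, 2 genes passed, Ggn (−0.68, adjusted p = 0.0146) and Vmn1r43 (−0.85, adjusted p = 0.00117), both under 3 FPKM and chosen after their values were seen, with a median of all genes of −0.265. After centring 58 differed, 37 higher and 21 lower with dTAG-13, and the count was 7403 without ortho-AP1867 replicate 1, 1 without ortho-AP1867 replicate 2 or 3 or dTAG-13 replicate 2, 6 without dTAG-13 replicate 1 and 140 without dTAG-13 replicate 3. It was 75 in a fit of the compared groups alone, 42 without a filter on low values and 1934 without the libraries whose median stands apart. Cholesterol synthesis (adjusted p = 0.00132), amino acid and ER stress (0.00222), ribosomal proteins (0.00264), p53 targets (0.0108), histone genes (0.0189) and FKBP family and CRBN ligase (0.0264) were placed above other genes and ERK pathway output (0.0189) below, each with adjusted p = 0.99 with an estimated correlation. Between ortho-AP1867 and AP1867, 5 genes passed and none after centring (877 at an unadjusted p under 0.05, 1034 before centring). They were Mir3096b (−7.77), a small RNA gene, and 9230115E21Rik (0.79), AU041133 (0.67), Vmn1r43 (0.64) and Ggn (0.60), all chosen after their values were seen. The count there was 133 without ortho-AP1867 replicate 1, 0 without ortho-AP1867 replicate 2 or AP1867 replicate 3 and 1 without AP1867 replicate 1. It was 86 in a fit of the compared groups alone and 8848 without the libraries whose median stands apart. The median of all genes was 0.189, and ribosomal proteins were placed below other genes (0.000263; 0.985 with an estimated correlation) although their median was 0.13.

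Between dTAG-13 and thalidomide none passed in limma (77 at an unadjusted p under 0.05, and 66 called in a fit of the compared groups alone), and after centring 27 differed, 24 higher and 3 lower. ERK pathway output was placed below other genes (adjusted p = 1.18e-05) and G2/M genes and cholesterol synthesis (each 0.0117), amino acid and ER stress (0.0181), histone genes (0.0187) and p53 targets (0.0286) above, each with adjusted p = 0.98 with an estimated correlation. Between dTAG-13 and dTAG-47 none passed in limma (173 at an unadjusted p under 0.05, and 65 called in a fit of the compared groups alone), and after centring 4 genes were lower with dTAG-13, Lss (−0.26, adjusted p = 0.00691), Thbs1 (−0.29), Aacs (−0.16) and C230081A13Rik (−0.33), chosen after their values were seen. Cholesterol synthesis was placed below other genes (4.01e-06, −0.12 relative to all genes), as was ERK pathway output (0.0011), with ribosomal proteins above (0.0184), each with adjusted p = 0.997 with an estimated correlation. Counts were 1 or 2 without dTAG-13 replicate 3 or thalidomide replicate 2 in the first pair, and without dTAG-13 replicate 3 or any dTAG-47 replicate in the second. The 95% confidence intervals of the 13 fixed genes ran from −0.70 to 0.13 for dTAG-13 against ortho-AP1867, −0.58 to 0.41 against thalidomide, −0.58 to 0.37 against dTAG-47 and −0.30 to 0.56 for ortho-AP1867 against AP1867. After centring they ran from −0.36 to 0.19, −0.39 to 0.21, −0.44 to 0.23 and −0.31 to 0.15, and the interval lay within 2-fold for 98.8%, 99%, 99% and 98.9% of genes, so a missed threshold leaves differences of these sizes open.

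The BET degrader dBET6 lowered most of the measured transcriptome, the median of all genes falling by 1.66 on the log2 scale. Against this fall, immediate early genes rose in 12 of 17 cases and fell in 5, with the neuronal activity gene Arc at 6.17, Nr4a1 at 5.17 and Junb at 4.54. The AP-1 subunit gene Fos stood at 69.7 ± 3.64 against 0.588 ± 0.0908 FPKM (SD, n = 3) and Egr1 at 881 ± 64.4 against 29.1 ± 4.57 FPKM. Histone genes rose in 4 of 10 cases and fell in 3 (10 risen after centring), with Hist1h2bc at 3.76 and Hist1h1c at 2.30. The matricellular gene Cyr61 (4.10), Colec11 (3.38), Hist1h2bk (2.49), the growth factor genes Hbegf (2.48) and Il11 (2.00), the p53 regulator Mdm2 (2.21), Ctgf (1.76) and Dusp6 (0.65) also rose. All 14 BET and transcription elongation genes fell, Hexim1, a P-TEFb inhibitor, from 21.3 ± 3.19 to 0.631 ± 0.0497 FPKM and Brd2 by −1.41 (0.79 after centring). Kras fell from 25.6 ± 4.24 to 1.40 ± 0.0558 FPKM. The largest falls were Gas1 (156 ± 23.5 to 2.08 ± 0.146 FPKM), Zmynd19 (−5.20), S1pr3 (−5.20), Sox4 (−5.19), Lurap1l (−5.17), Zfp637 (−4.77), Slc38a2 (−4.72) and Cdc42ep3 (−4.67). All 17 G2/M genes fell, with the mitotic kinase Plk1 at −4.13 and Ccna2 at −3.93. ERK pathway output had 15 of 19 fallen, with the RAS inhibitors Spred1 at −3.90 and Spred2 at −3.53 and Fosl1 at −3.30.

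In all 10781 genes differed with dBET6, 111 higher and 10670 lower, of which 70 and 8269 by at least 2-fold. After centring 10038 differed, 7031 higher and 3007 lower, so the share of higher genes moved from 1.03% to 70%, and 6682 genes passed with opposite signs before and after. Centring subtracts each library's own median, which averaged 1.841 with dBET6 and 4.034 with DMSO. That gap is wider than the median gene change of −1.663. Centred changes therefore lie above changes relative to the median gene, and part of the 70% and of the opposite signs comes from this. Without a filter on low values 19033 differed. All 30 ribosomal protein genes fell (Rpl4 at −0.67) but less than the median and rose after centring (Rpl4 at 1.52), and of 19 extracellular matrix genes 18 fell as deposited and 18 rose after centring. Camera placed immediate early genes (adjusted p = 1.84e-57; 0.00449 with an estimated correlation) and histone genes (1.47e-19; 0.00739) above other genes, the 2 calls of 121 in the data that held with an estimated correlation. Both were lost when the correlation was estimated on centred values (adjusted p = 0.207 and 0.478). Contractile targets (6.19e-14; adjusted p = 0.223 with an estimated correlation), ribosomal proteins (6.19e-11; 0.712), growth factors and proteases (2.54e-06; 0.555), extracellular matrix (1.58e-05; 0.714), p53 targets (0.000248; 0.714) and ERK pathway output (0.0131; 0.914) were placed above other genes although their medians were −0.34, −0.60, −0.93, −0.67, −1.07 and −1.29. G2/M genes were placed below (0.0131; 0.914), with a median of −2.75, and BET and transcription elongation genes were not called (0.136).

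With the correlation estimated on centred values, a setting chosen after the data were seen, 25 of the 121 list calls held. ERK pathway output held in KRAS against control cells (adjusted p = 0.0409), with dTAG-13 at 4 h (0.0113) and 8 h (0.0389), with trametinib at 4 h (0.00277) and 8 h (0.0274), and in dTAG-13 against trametinib at 4 h (0.00472) but not at 8 h (0.2). In parental cells it held for dTAG-13 against DMSO (0.00129), thalidomide (0.0359) and dTAG-47 (0.045). Growth factors and proteases held with dTAG-13 at 4 h (0.0167) and 8 h (0.0389), with trametinib at 4 h (0.0149) and 8 h (0.0432) and with dTAG-13 in parental cells (0.0299). G1/S genes held with dTAG-13 at 8 h (0.0389), trametinib at 8 h (0.0323) and dTAG-13 at 8 h against 4 h (0.0224). Contractile targets held in KRAS against control cells (0.0409) and in dTAG-13 at 8 h against 4 h (0.0438), and histone genes with dTAG-13 at 4 h (0.0168). Cholesterol synthesis held in parental cells with dTAG-47 (3.77e-05) and for dTAG-13 against DMSO (0.0203), ortho-AP1867 (0.0301) and dTAG-47 (0.0029), and amino acid and ER stress with dTAG-13 (0.0203).

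**Figure D3:**
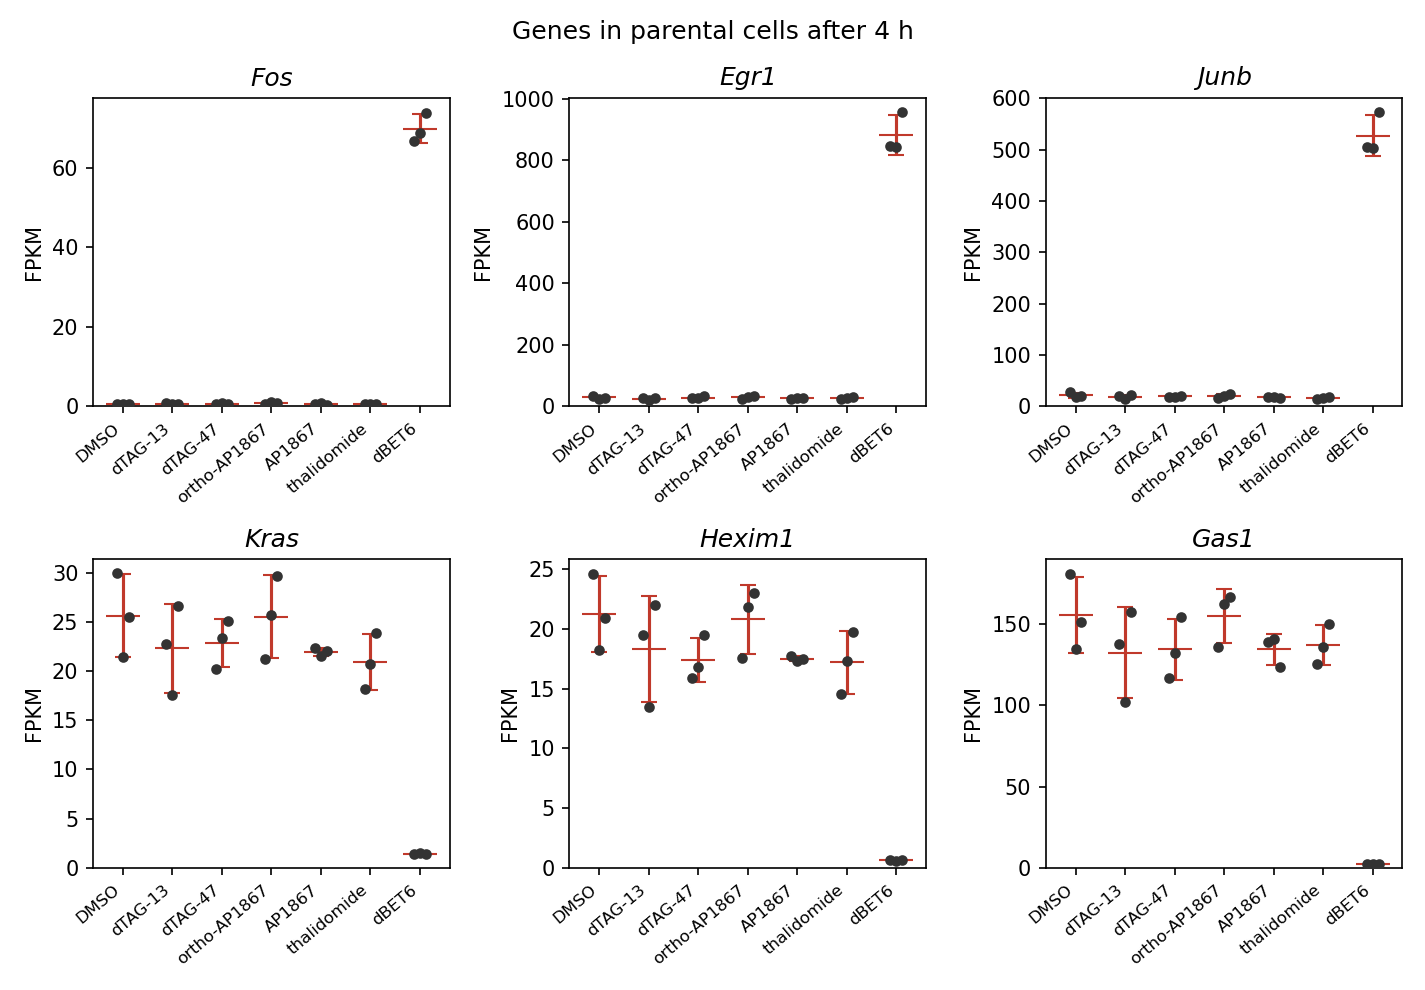
FPKM of 6 genes (vertical axes) in the 7 groups of parental cells (horizontal axes), 1 point per library and the group mean ± SD in red. Fos averaged 69.7 FPKM with dBET6 against 0.588 FPKM with DMSO, and Kras averaged 1.40 FPKM against 25.6 FPKM.

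**Figure D4:**
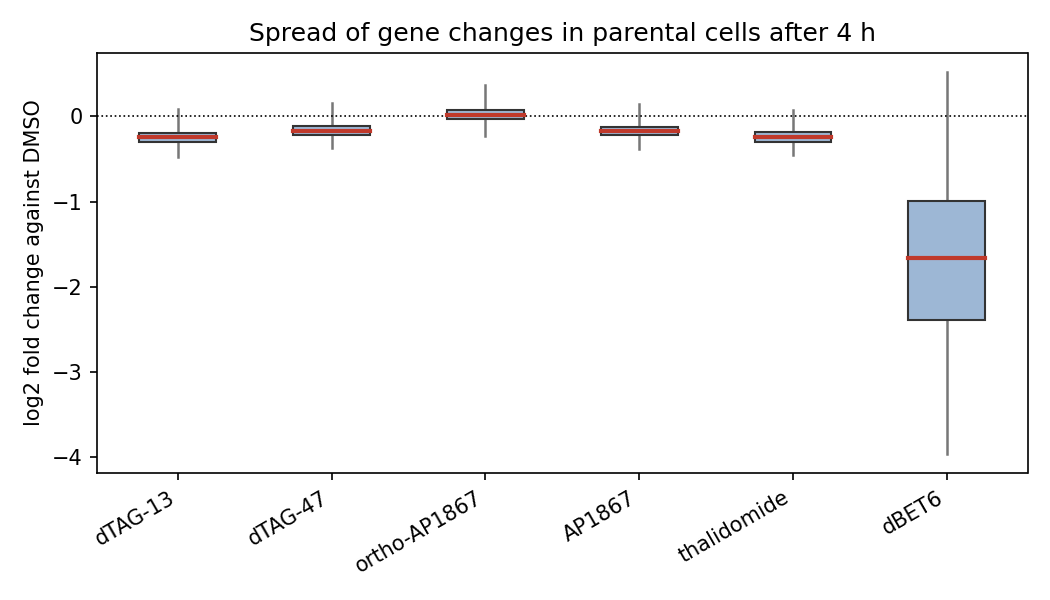
Log2 fold change against DMSO over the tested genes (vertical axis) for each compound in parental cells (horizontal axis), with bars from the lower to the upper quartile, the median in red and lines from the 1st to the 99th percentile. The median was −1.66 with dBET6 and between −0.25 and 0.02 with the other compounds. After centring, which shifts the dBET6 changes by more than their median, 70% of the genes changed by dBET6 were higher.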

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

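Among the tests below, those of the floor of the table, of the scatter of the spike-in scale, of RNA loss with the fall of ERK output, and all those on ERK pathway output with dTAG-13 and trametinib were chosen only after the result was seen.

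Libraries of a treatment differed between the time points. Without a DMSO group at 4 h, an effect of the treatment cannot be told apart from time or handling. With dTAG-13 in KRAS cells 5522 genes differed between 8 h and 4 h as deposited and 962 after centring of each library. With trametinib the numbers were 2915 and 4046. As deposited they ran from 473 to 9384 and from 171 to 3076 when 1 library was left out. The change from 4 h to 8 h itself differed between dTAG-13 and trametinib for 8884 genes, 8878 of them higher with dTAG-13, with a median of 0.67, and after centring for 5 genes (1 higher, 4 lower). Among the spike-ins, which no comparison used, 22 of 51 differed between dTAG-13 and trametinib at 8 h (11 higher, 11 lower, median 0.08, from −0.94 to 0.54). Of 49 spike-ins, 1 differed between dTAG-47 and DMSO, 1 between dBET6 and DMSO, 1 between dTAG-13 and thalidomide and 1 between ortho-AP1867 and AP1867 in parental cells.

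The median of all genes shifted between the groups of the KRAS experiment, by −0.363 with dTAG-13 at 4 h and −0.272 with trametinib at 8 h but by 0.012 and 0.013 with dTAG-13 at 8 h and trametinib at 4 h. In a permutation test of the F ratio (p = 0.0132), library medians differed among the 6 groups beyond the scatter within groups (SD 0.175). The 6 include control cells, outside these shifts, so scatter of the spike-in scale stays open as the cause. A loss of RNA that goes with the fall of ERK output could give lower medians in all 4 treated groups, and the highest of them was 0.013 with a standard error of 0.143. That value lies above the bound of −0.1 by less than its standard error. Such a loss thus cannot be told apart from handling that follows the groups, as on a shared day, which the labels do not give.

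With dBET6, 12 of 17 immediate early genes rose and 5 fell and 4 of 10 histone genes rose and 3 fell, while most genes fell, and both list calls were lost with the correlation estimated on centred values (adjusted p = 0.207 and 0.478). A single scale factor per library as the cause is argued against by the spread of the fold changes over genes at 5 FPKM or more in DMSO, whose interquartile range was 1.41 against at most 0.0891 for the other compounds. Values near the floor of the table are argued against as well, since 13 of the 16 immediate early and histone genes called higher (81.2%) had a DMSO mean of 1 FPKM or more. The loss of BET proteins, which the treatment aims at, may account for the pattern as a hypothesis, but the design holds no other BET ligand and it was not tested apart from other actions of dBET6. Reads of histone mRNA in a poly(A) library depend on polyadenylated forms, and this was not tested.

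In KRAS cells at 8 h, ERK pathway output was higher with dTAG-13 than with trametinib in 14 of 19 members and lower in 1, a list call with adjusted p = 0.971 with an estimated correlation and 0.2 with that on centred values, while at 4 h 5 were higher and 2 lower as deposited and 14 and 0 after centring. A scale difference between the libraries as the whole cause is argued against by the centred median difference of the list at 8 h, 0.482 with a spread of 0.06 between libraries. An effect of dTAG-13 without the fusion stays open at 8 h, since all parental libraries were treated for 4 h, when the list stood at −0.157 relative to all genes (standard error 0.028). A return to the level of control cells could give such a difference, and the list median minus control cells at 8 h was −0.173 with dTAG-13 and −1.013 with trametinib (standard error 0.143), and 0.034 and −0.513 after centring. The members with dTAG-13 went both ways, 1 higher and 7 lower than in control cells as deposited and 6 higher and 5 lower after centring, so a return of the list stays open, by a condition on the members that was added after the medians were seen.

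Each comparison was set against the 10 divisions of its 6 libraries into 3 and 3, which cannot give a share under 0.1. As many genes as the real number, the real division included, came from 1 of the 10 divisions for KRAS against control (2972, highest other 1), dTAG-13 at 4 h (5471, highest other 3409), trametinib at 4 h (1578, highest other 0) and trametinib at 8 h (4765, highest other 1). The same held, with 1 of the 10, for trametinib at 8 h against 4 h (2915, highest other 1), dTAG-13 against trametinib at 4 h (5372, highest other 2), dBET6 (10781, highest other 0) and ortho-AP1867 against AP1867 (5, highest other 2). From 2 of the 10 divisions came as many for dTAG-13 at 8 h (2580, highest other 3112), dTAG-13 at 8 h against 4 h (5522, highest other 6425) and dTAG-13 against trametinib at 8 h (3595, highest other 4511). Where no gene was called, all 10 divisions give as many by construction, so the number says nothing for parental dTAG-13 (0, highest other 2), dTAG-47 (0, highest other 2), AP1867 (0, highest other 1), thalidomide (0, highest other 1), dTAG-13 against thalidomide (0, highest other 4775) and dTAG-13 against dTAG-47 (0, highest other 1). It was 4 of 10 for ortho-AP1867 (1, highest other 7123) and 7 of 10 for dTAG-13 against ortho-AP1867 (2, highest other 9472). The divisions that called 7123 genes with ortho-AP1867, 9472 in dTAG-13 against ortho-AP1867 and 4775 in dTAG-13 against thalidomide, beside real numbers of 1, 2 and 0, point to a structure of the samples that does not follow the groups. Other divisions also exceeded the real number for dTAG-13 at 8 h (3112), dTAG-13 at 8 h against 4 h (6425) and dTAG-13 against trametinib at 8 h (4511).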

How the results depend on the processing

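The runs without the libraries whose median stands apart, without the dBET6 libraries and with an estimated correlation on centred values were chosen only after the data were seen, and the other alternatives were planned. Of 607 results for named genes, 445 passed the threshold and 300 of these passed it in the same direction under every alternative, or 322 under every alternative but centring. Of the 121 list calls, 117 held with a pseudocount of 0.1, 106 after centring, 120 with the replicate block, 2 with an estimated correlation and 25 with an estimated correlation on centred values. The depth of the libraries is unknown, so what it limits was not examined, and where a cause is not given by the construction of an alternative, the cause was not tested.

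Centring moved the number of changed genes to 5678 for dTAG-13 at 8 h, 4086 for trametinib at 4 h, 962 for dTAG-13 at 8 h against 4 h, 1226 and 5467 for dTAG-13 against trametinib at 4 h and 8 h. In parental cells it moved the number to 52 for dTAG-13, 32 for dTAG-47, 4 for ortho-AP1867, 2 for thalidomide, 58, 27 and 4 for dTAG-13 against ortho-AP1867, thalidomide and dTAG-47, and 0 for ortho-AP1867 against AP1867. Among named results that passed before or after centring, it turned the sign of Brd2 in KRAS against control (0.149), Rpl23 (0.048) and Fkbp1a (0.006) with dTAG-13 at 4 h, Hexim1 with trametinib at 8 h (0.27), Spry4 with dTAG-13 at 8 h against 4 h (−0.038), and Crbn with trametinib at 8 h against 4 h (0.267). It also turned H2afz (0.062), Hexim1 (0.028) and Brd2 (0.017) in dTAG-13 against trametinib at 4 h. With dBET6 it turned Fkbp1a (1.563), Rpl4 (1.524), Rpl18 (1.507), Rpl3 (1.483), Rps6 (1.48), Col1a1 (1.342), Col1a2 (1.334), Ccnd1 (1.286), Myc (1.216), Etv4 (1.135), Lox (1.114), Vcl (0.881), H2afz (0.814), Brd2 (0.788), Spry4 (0.607) and Etv5 (0.216). It removes the fall of the library medians, which was larger than the median change of all genes. Of the other named results 41 became weaker and 16 stronger.

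Without a filter on low values the number was 3469 for dTAG-13 at 8 h against 4 h, 466 for trametinib at 8 h against 4 h, and 140 for dTAG-13 against trametinib at 8 h. In parental cells it was 19033 for dBET6, 1 for dTAG-47, 2 for ortho-AP1867, 42 for dTAG-13 against ortho-AP1867, 1 for dTAG-13 against dTAG-47 and 9 for ortho-AP1867 against AP1867, and 89 named genes became weaker. At 5 FPKM or more it was 1 for parental dTAG-13, 0 for ortho-AP1867, 0 and 1 for dTAG-13 against ortho-AP1867 and thalidomide, and 1 for ortho-AP1867 against AP1867. With a pseudocount of 0.1 it was 1 for parental dTAG-13, 1 for dTAG-13 against ortho-AP1867 and 2 for ortho-AP1867 against AP1867. With the replicate block, whose numbers are shared by the libraries only as numbers, it was 1840 for trametinib at 8 h against 4 h, 1 for parental dTAG-13, 1 for dTAG-13 against thalidomide and 2 for ortho-AP1867 against AP1867.

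With only the groups compared in the fit the number was 1471 for dTAG-13 at 8 h, and 2519 for dTAG-13 at 8 h against 4 h. In parental cells it was 59 for parental dTAG-13, 69 for dTAG-47, 76 for ortho-AP1867, 84 for AP1867, 63 for thalidomide, 75, 66 and 65 for dTAG-13 against ortho-AP1867, thalidomide and dTAG-47, and 86 for ortho-AP1867 against AP1867. Without the libraries whose median stands apart it was 1666 for dTAG-13 at 8 h, where the lone library left is assumed to vary like the other groups, 2501 for trametinib at 4 h, 5403 for trametinib at 8 h against 4 h, 976 for ortho-AP1867, 1934 for dTAG-13 against ortho-AP1867 and 8848 for ortho-AP1867 against AP1867. Without the dBET6 libraries it was 1 for dTAG-13 against ortho-AP1867 and 1 for ortho-AP1867 against AP1867.

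Leaving out each library in turn gave from 1819 to 2947 genes for KRAS against control, 3713 to 7416 and 1956 to 3078 for dTAG-13 at 4 h and 8 h, and 1178 to 1733 and 2999 to 6205 for trametinib at 4 h and 8 h. It gave 473 to 9384 for dTAG-13 and 171 to 3076 for trametinib at 8 h against 4 h, and 2560 to 5933 and 66 to 6340 for dTAG-13 against trametinib at 4 h and 8 h. The lowest came without control replicate 1, KRAS DMSO replicate 3, dTAG-13 8 h replicate 3, trametinib 4 h replicate 1, KRAS DMSO replicate 3, dTAG-13 8 h replicate 1, trametinib 4 h replicate 2, dTAG-13 4 h replicate 3 and dTAG-13 8 h replicate 1, in the same order. In parental cells it gave 0 to 1 for dTAG-13, 0 to 1 for dTAG-47, 0 to 19 for ortho-AP1867, 0 to 1 for AP1867, 0 to 2 for thalidomide, and 10601 to 10777 for dBET6. It gave 1 to 7403, 0 to 2 and 0 to 2 for dTAG-13 against ortho-AP1867, thalidomide and dTAG-47, and 0 to 133 for ortho-AP1867 against AP1867, where 7403, 133 and 19 came without ortho-AP1867 replicate 1. Over all omissions 370 of the named gene results became weaker and 24 stronger, and 3248 stayed on their side of the threshold.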

Other observations

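The comparisons of treated KRAS cells with control cells were chosen only after the data were seen. In KRAS cells with dTAG-13 at 8 h, extracellular matrix genes were still below control cells, 10 of 19 lower and 1 higher in limma, with a list median of −0.62 as deposited and −0.41 after centring (10 lower and 3 higher). Amino acid and ER stress genes, lower in KRAS cells than in control cells with DMSO, were lower in 9 of 14 cases with dTAG-13 at 8 h (median −0.67, and −0.47 after centring). G1/S and DNA replication genes, of which 1 of 20 was lower in KRAS DMSO cells than in control cells, were lower than control cells in 19 of 20 cases with dTAG-13 at 8 h (median −0.80, and −0.60 after centring). They were lower in all 20 cases with trametinib at 8 h (median −1.29, and −0.79 after centring). Cholesterol synthesis genes were above control cells after centring in 12 of 16 cases with DMSO, 13 and 15 with dTAG-13 at 4 h and 8 h, and 14 and 13 with trametinib at 4 h and 8 h, against 4, 0, 6, 5 and 2 as deposited. None was below control cells except 3 with dTAG-13 at 4 h as deposited (list median −0.17). In all 8383 and 4012 genes differed from control cells with dTAG-13 at 4 h and 8 h and 3477 and 7241 with trametinib at 4 h and 8 h, and after centring 5622, 5889, 5269 and 6567. Single genes differed in how far they moved back, in values chosen among 34 genes looked at. Tmem176b stood at −6.78 against control cells with dTAG-13 at 8 h (−6.81 with DMSO), Cxcl5 at −4.51 (−4.62), Acta2 at −3.61 (−3.93), Tagln at −3.73 (−3.90) and Spry1 at −1.67 (−1.69). Sema7a moved to 0.55 (3.80 with DMSO), Lox to −1.40 (−3.24), Col1a1 to −1.19 (−2.83) and Col3a1 to 0.51 (−1.13).

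The measured fall with dBET6 differed with the level of a gene in DMSO. Among genes with a DMSO mean under 1 FPKM none was at least 2-fold lower (259 genes, median −0.31), and among those of 1 to 5 FPKM 60.6% were (2144 genes, median −1.19), where the pseudocount of 1 FPKM limits the fold change. Among genes with a DMSO mean of 5 to 20 FPKM 88.2% were at least 2-fold lower (3954 genes, median −2.13), among those of 20 to 100 FPKM 83.2% (3602 genes, median −1.90) and among those of 100 FPKM or more 44.2% (1096 genes, median −0.93). Of the 111 genes called higher 66 had a DMSO mean of 1 FPKM or more, and of the 10670 called lower 7393 had a dBET6 mean of 1 FPKM or more.

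Across genes in parental cells, the effects of dTAG-13 and dTAG-47 correlated with r of 0.556 and rho of 0.476. For dTAG-13 and dBET6 r was 0.195 and rho 0.206. Simulated unchanged groups sharing DMSO libraries gave a mean r of 0.493. The covariances (0.0236 and 0.0406) exceeded the simulated mean by 0.00327 and 0.0202 but lay within the simulated range (0.00211 to 0.0502). Sharing alone may thus give all of each excess. With a pseudocount of 0.1 r was 0.527 and 0.127.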
